A study of Homo sapiens with 9 samples.

How the data were processed

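MicroRNA (miRNA) expression was measured with an Illumina bead array in 9 samples of human ovarian carcinoma cells, 3 of each of 3 lines. The lines are parental IGROV-1, IGROV-1/OHP and IGROV-1/Pt1. The series design text calls the 3 samples of a line independent biological replicates. Each array is a 1-colour hybridisation of biotin-labelled total RNA that was extracted with Trizol and cleaned on a column with DNase treatment, per the labels' protocols. Groups were taken from the sample titles.

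The deposited value table holds linear probe intensities of 1145 probes, and the submitters' processing notes name BeadStudio, with no version. The normalization and background settings are not given in the sources used here. The sorted intensities of the 9 arrays differed by at most 2.69% at any rank, which is the form that quantile normalization gives, so the deposited intensities were taken as already quantile-normalized and were not normalized again. Quantile normalization gives every array the same distribution, so a change in the total amount of miRNA between the lines cannot be seen in these values. The intensities ran from 41.1 to 38631, with array medians of 240.2 to 241.2. The lowest values lie well above 0, so a background floor remains in them and fold changes of dim probes are understated. At the bright end, one probe held the highest intensity on every array.

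A second deposited table of signals and detection p-values was not used. Its 18 columns are named by 9 positions on 1 chip, and these names match no sample label. A match of the columns to samples by their values was not tried. The design, the alternatives, the miRNA lists and the rule for named probes were fixed before the data were examined. That plan had taken the signals, a background correction tied to detection p (neqc) and a filter on detection p from that table. The deposited normalized intensities were used in its place, on the log2 scale with no pseudocount, and the filter was set on intensity after the data had been seen. The level was 2 times the mode of all intensities (83.4), which is 167, and a probe was tested when it reached this level on at least 3 of the 9 arrays, whichever line they came from. This left 705 probes, of which 555 reached the level on all arrays, and put aside 440. The level is a setting made here and not a detection call.

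The probes carry Illumina identifiers. Neither table pairs them with miRNA names, and 0 of the 1145 identifiers occurred in the reference gene table, so no miRNA, family or genomic position is named here. The 30 lists of miRNA families, clusters and cell type markers fixed in the same plan could not be matched to probes and were not tested. The word probe is therefore used in place of a miRNA name.

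The log2 intensities were fitted with limma 3.58.1 in R 4.3.3 as 3 group means over all 9 arrays, which gave 6 residual degrees of freedom. The 3 comparisons were moderated with eBayes (prior degrees of freedom 1.51, prior SD 0.18 on the log2 scale) and tested two-sided. Adjusted p-values are limma's after Benjamini-Hochberg correction over the 705 probes of a comparison, with a threshold of 0.05. Levels are means ± SD of the deposited intensities. Fold changes come from mean log2 intensities. Where a probe lay below the level on all 3 arrays of a line, its fold is given as a lower bound against the level. Where some arrays of a line reached the level, their number is given, and folds and ranges called measured can include levels below it. The rule for named probes took the 12 largest rises and 12 largest falls per comparison among probes past the threshold whose arrays did not overlap. Because the probes have no names, the first 2 in each direction are printed. The rule also asked for members of the lists and for individual miRNAs, which needs names, and for the largest shared and opposite changes, which are summarised as counts and medians.

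The fit was tested on simulated data for IGROV-1/OHP against parental cells, with the means and spreads of the 705 probes and 200 of them changed. It recovered 43.3% of the 1.5-fold changes, 77.6% of the 2-fold changes and 93.9% of the 4-fold changes. False calls were 2.72% of all calls. This was a single draw of normal noise, with 1 spread per probe taken over all 3 lines. The median SD was 0.25 in IGROV-1/OHP and 0.22 in parental cells against 0.16 in IGROV-1/Pt1. Recovery in the real comparison can therefore be lower. The precision is limited by the 3 arrays per line, with a median standard error of 0.20 on the log2 scale. Calls shared by comparisons that use the same arrays were set beside 100 simulations of 3 unchanged lines, and beside the overlap of independent lists of the same lengths. Alternatives covered background correction, scaling, the filter, the arrays in the fit, the variance prior, array weights (estimated gene by gene, as the REML estimate did not converge), a replicate block, thresholds and leaving out each array. A chip block was not tried. The column names of the unused table carry 1 chip number, which leaves no block to fit if they stand for these 9 arrays. Figures were drawn with matplotlib 3.10.9.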

Results

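The data describe miRNA levels in a human ovarian carcinoma cell line, IGROV-1, and in a pair of lines derived from it that are resistant to platinum drugs. IGROV-1/Pt1 was derived by exposure to cisplatin and IGROV-1/OHP by exposure to oxaliplatin. Both drugs are platinum compounds that form DNA adducts. Cisplatin carries ammine and chloride ligands, whereas oxaliplatin carries a diaminocyclohexane ligand and an oxalate leaving group. The labels give no dose and no time. Each line was represented by 3 arrays. The 3 comparisons ask which miRNAs differ between each resistant line and the sensitive parent, and which differ between the resistant lines.

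The lines separated on the first principal components of the 705 tested probes. The first, with 49.1% of the variance, set IGROV-1/Pt1 apart from the other lines, and the second, with 24.6%, parted IGROV-1/OHP from the parental cells. IGROV-1/Pt1 had the tightest replicates, with correlations of log2 intensity between arrays of 0.981 to 0.994. The range was 0.950 to 0.979 in parental cells and 0.941 to 0.984 in IGROV-1/OHP. Between these lines some correlations lay above the lowest within them, up to 0.956 for IGROV-1/OHP replicate 1 with parental replicate 3. The median SD of a probe was 0.16 in IGROV-1/Pt1, 0.22 in parental cells and 0.25 in IGROV-1/OHP on the log2 scale (n = 3 each). On parental replicate 1, 20 probes were at least 4-fold brighter than on parental replicate 2, whereas 2 were as much dimmer. In IGROV-1/OHP, 26 probes differed at least 4-fold between replicates 2 and 3.

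**Figure D1:**
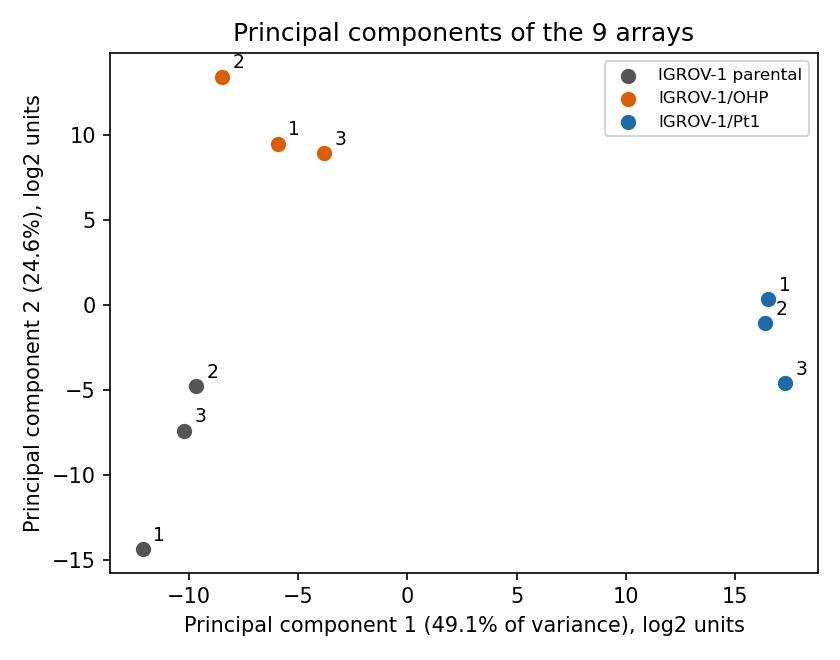
Scores of the 9 arrays on principal components 1 and 2 of the log2 intensities of the 705 tested probes (log2 units), coloured by line, with the replicate number beside each point. The 3 IGROV-1/Pt1 arrays lie together between 16.4 and 17.3 on component 1, and parental replicate 1 lies at -14.3 on component 2, away from parental replicates 2 and 3 at -4.78 and -7.38.

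The oxaliplatin-resistant line differed from the parental cells at 93 of the 705 probes, 55 higher and 38 lower in IGROV-1/OHP (limma, adjusted p below the threshold). As measured, 30 of these were at least 2-fold higher and 23 at least 2-fold lower, and 28 and 22 with probes below the filter level on all arrays of a line taken at their bounds. The largest measured rise was at ILMN_3168804, which lay below the filter level on all parental arrays (61.2 ± 9.8, SD, n = 3). It reached 1097 ± 191 in IGROV-1/OHP (n = 3), at least 6.50-fold higher (measured log2 change 4.16, SE 0.17, limma adjusted p = 6.2e-06). At this bound its rise is smaller than that of ILMN_3168389. ILMN_3168389 rose 12.5-fold, from 1145 ± 188 to 14243 ± 664 (log2 change 3.65, SE 0.15, limma adjusted p = 6.2e-06). The largest falls were at ILMN_3168064, from 9181 ± 1205 to 233 ± 103 (log2 change -5.42, SE 0.40, limma adjusted p = 1.96e-04), and at ILMN_3168701, from 2767 ± 212 to 139 ± 44.5 (log2 change -4.36, SE 0.35, limma adjusted p = 2.00e-04). In IGROV-1/OHP, ILMN_3168064 reached the filter level on 2 of the 3 arrays and ILMN_3168701 on 1. As measured, the 12 probes with the largest rises spanned 3.50-fold to 17.9-fold and the 12 with the largest falls 2.89-fold to 42.7-fold, and some of these folds are against levels below the filter level.

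Among probes with a mean level of 10000 or more in the pair of lines, 12 of 143 passed the threshold in IGROV-1/OHP against parental cells. Between 1000 and 10000, 42 of 219 passed, and below 1000, 39 of 343. All 93 called probes had no overlap between the arrays of the lines. Such separation was seen at 33.0% of all tested probes, where chance gives 10%. An unadjusted p below 0.05 was found at 196 probes. The balance of directions depended on the scaling, with 47 higher and 49 lower after cyclic loess and 42 higher and 51 lower after median scaling. Leaving out IGROV-1/OHP replicate 1 reduced the count to 60, with 32 higher, and without replicate 3 there were 36 higher. With array weights the count was 139, with 87 higher. None of the 20 probes raised on parental replicate 1 was among the 93. The same held for the 26 that differed between IGROV-1/OHP replicates 2 and 3. These probes were chosen for a wide spread within a line, which makes a call unlikely. Their absence therefore does not show that these arrays had no effect. Without parental replicate 1, 29 of the 93 calls were lost, and without IGROV-1/OHP replicate 2, 26 were lost. Each other array cost more calls, 38 and 31 for IGROV-1/OHP replicates 1 and 3 and 33 for each of parental replicates 2 and 3. The losses are therefore not particular to the arrays with these probes.

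The cisplatin-resistant line differed from the parental cells at 126 probes, 76 higher and 50 lower in IGROV-1/Pt1 (limma). A measured change of at least 2-fold was seen at 82 of them, 55 higher and 27 lower, and 13 were at least 8-fold higher against 3 at least 8-fold lower. At their bounds these were 49 and 23 at 2-fold and 11 and 3 at 8-fold. ILMN_3167116 lay below the filter level on all parental arrays (81.7 ± 24.2, n = 3) and was among the bright probes in IGROV-1/Pt1 at 16825 ± 1020 (n = 3). It was at least 101-fold higher (measured log2 change 7.73, SE 0.24, limma adjusted p = 6.8e-07). ILMN_3167208, which reached the filter level on 1 of the 3 parental arrays, rose from 146 ± 39.0 to 25088 ± 1865, 176-fold as measured (log2 change 7.46, SE 0.24, limma adjusted p = 6.8e-07). The largest fall was at ILMN_3168483, one of the bright probes of the parental cells, which dropped from 24787 ± 1049 to 327 ± 70.9, or 77.0-fold (log2 change -6.27, SE 0.16, limma adjusted p = 1.6e-07). ILMN_3167344 fell 14.3-fold, from 7176 ± 1581 to 600.2 ± 483 (log2 change -3.84, SE 0.56, limma adjusted p = 0.0021). Its IGROV-1/Pt1 replicate 3 stood at 1157 against 297 and 347 on the others, and without that array the log2 change was -4.46.

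The 12 largest rises in IGROV-1/Pt1 spanned 10.5-fold to 212-fold and the 12 largest falls 4.59-fold to 77.0-fold, as measured. Some of these folds, including both ends of the rises, are against levels below the filter level. Of the probes with a mean level of 10000 or more, 15 of 143 passed the threshold, as did 54 of 219 between 1000 and 10000 and 57 of 343 below 1000. The arrays did not overlap at 41.4% of all tested probes, where chance gives 10%, and 213 probes had an unadjusted p below 0.05. Of the 20 probes raised on parental replicate 1, 1 was among the 126, and their spread within the parental line makes a call unlikely. With array weights the count rose to 219, 115 higher and 104 lower.

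The resistant lines were compared directly, and 117 probes differed (limma), 61 higher and 56 lower in IGROV-1/OHP than in IGROV-1/Pt1. Of the 63 that differed at least 2-fold as measured, 25 were higher in IGROV-1/OHP and 38 higher in IGROV-1/Pt1, and 21 and 35 at their bounds. ILMN_3168483 was 78.9-fold higher in IGROV-1/OHP, at 25392 ± 1190 (log2 difference 6.30, SE 0.16, limma adjusted p = 1.6e-07). In IGROV-1/OHP its log2 difference from parental cells was 0.03, with a 95% interval of -0.33 to 0.40. ILMN_3167344 was 12.5-fold higher in IGROV-1/OHP (log2 difference 3.64, SE 0.56, limma adjusted p = 0.0042), and without IGROV-1/Pt1 replicate 3 the log2 difference was 4.26. In the other direction, ILMN_3167656 was at 161 ± 99.8 in IGROV-1/OHP and 15729 ± 370.2 in IGROV-1/Pt1, 110.2-fold lower in the former as measured (log2 difference -6.78, SE 0.39, limma adjusted p = 1.8e-05). It reached the filter level on 1 of the 3 IGROV-1/OHP arrays, and ILMN_3167116 on 2. ILMN_3167116 was 85.9-fold lower in IGROV-1/OHP as measured (log2 difference -6.42, SE 0.24, limma adjusted p = 2.1e-06).

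An unadjusted p below 0.05 was found at 223 probes between the resistant lines. After cyclic loess the split of calls was 48 higher and 77 lower in IGROV-1/OHP, and after median scaling 41 higher and 78 lower. Leaving out IGROV-1/Pt1 replicate 1, 2 or 3 reduced the count to 76, 71 or 77, with 36, 35 or 34 higher and 40, 36 or 43 lower, and array weights raised it to 200, with 116 higher. Lower calls also outnumbered higher ones without IGROV-1/OHP replicate 1 (34 higher, 49 lower), without parental replicate 2 (44 higher, 51 lower) and with no filter (51 higher, 55 lower).

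Both resistant lines differed from the parental cells in the same direction at 44 probes, 32 higher and 12 lower. Simulated lines with no effect at all that shared the parental arrays gave at most 1 such probe, a value that leaves out real effects, and independent lists of the same lengths, which leave out the shared arrays, would share 8.62. The median rise of the 32 probes was 1.24 in IGROV-1/OHP and 1.78 in IGROV-1/Pt1 on the log2 scale, and the median change of the 12 lower probes was -1.23 and -1.89. With probes below the filter level on all arrays of a line set at their bounds, these medians were 1.18 and 1.57 for the higher and -1.23 and -1.82 for the lower probes. ILMN_3168804 and ILMN_3168389 did not pass the threshold between the resistant lines, with 95% intervals of the log2 difference between the lines of -0.46 to 0.31 and -0.19 to 0.49. Among the 44 probes, these were the 2 at least 8-fold higher in both resistant lines as measured (1 at its bound), and 0 were 8-fold lower in both. ILMN_3167116 and ILMN_3167208 passed the threshold in both lines but stood at different levels, 199.8 ± 50.7 and 512 ± 135 in IGROV-1/OHP against 16825 ± 1020 and 25088 ± 1865 in IGROV-1/Pt1 (n = 3 each). Against the filter level, ILMN_3167116 was at least 1.17-fold higher in IGROV-1/OHP than in parental cells. In all, 13 of the 44 shared probes also differed between the resistant lines. For 25 of the other 31, the 95% interval of the difference lay within 2-fold.

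The same parental arrays were used in both comparisons, so part of the excess over either value can come from them. With the parental arrays divided, 1 array against one resistant line and the other pair against the other line, the count was between 16 and 38. This division also leaves fewer arrays in each comparison, so it does not show how much the shared arrays contribute. With array weights and undivided arrays the count was 73. Across probes the changes in the resistant lines correlated at 0.46 where simulated unchanged lines gave 0.49, and their covariance was 0.38 against 0.049 in the simulation, a difference of 0.33. Genes are not independent replicates in this correlation. Without IGROV-1/OHP replicate 1 the number of probes higher in both lines was 21.

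**Figure D2:**
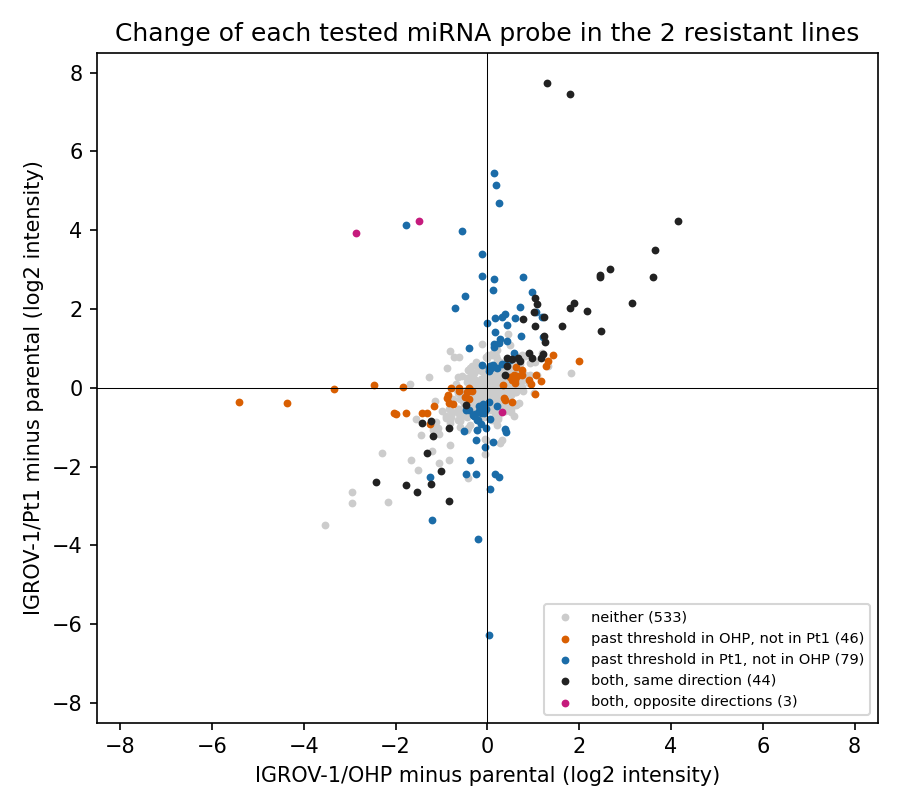
Log2 change against parental cells of each of the 705 tested probes in IGROV-1/OHP (x axis) and IGROV-1/Pt1 (y axis), each point a probe, coloured by whether it passed the adjusted p threshold in 1, both or neither comparison. The 44 probes called in the same direction lie at the upper right and lower left, and the largest measured rise in IGROV-1/Pt1 is 7.73.

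Probes that set 1 line apart from both others were more numerous for IGROV-1/Pt1 than for IGROV-1/OHP. By the same rule the 44 shared probes, 32 higher and 12 lower in both resistant lines, set the parental cells apart. With 1 line of each kind, a shared change cannot be told from a trait of the parental cultures. IGROV-1/Pt1 was higher than both other lines at 36 probes and lower at 32. Independent lists would share 6.04 and 4.33, and the simulation with no effect gave at most 1. Among these probes and as measured, 10 were at least 8-fold higher in IGROV-1/Pt1 than in both other lines (9 at their bounds), 3 of them below the filter level on all arrays of those lines, and 2 probes, ILMN_3168483 and ILMN_3167344, were at least 8-fold lower. IGROV-1/OHP was higher than both other lines at 13 probes and lower at 14, against 4.76 and 3.02 for independent lists. Among these, 0 were at least 8-fold higher in IGROV-1/OHP than in both other lines, and 3 were at least 8-fold lower as measured (2 at their bounds), including ILMN_3168064 and ILMN_3168701. In 3 probes the resistant lines departed from the parental cells in opposite directions, where independent lists would share 8.0 and the simulation with no effect gave 0. The largest difference was at ILMN_3167656, which fell 7.27-fold as measured in IGROV-1/OHP (limma adjusted p = 0.0034) and rose 15.2-fold in IGROV-1/Pt1 (limma adjusted p = 2.95e-04). In all of these counts, the comparisons that are joined share the arrays of 1 line. Independent lists leave this out, so part of each excess can come from those arrays. Sharing the parental arrays also makes opposite calls rarer than in independent lists.

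The number of probes higher in IGROV-1/OHP than in both other lines was unstable. It was 6 after median scaling, 34 with array weights, and between 4 and 7 when any of IGROV-1/OHP replicates 1 and 3, the IGROV-1/Pt1 replicates or parental replicates 2 and 3 was left out. The 14 probes lower in IGROV-1/OHP became 22 after cyclic loess or with array weights and 23 after median scaling. With array weights there were 55 probes lower in IGROV-1/Pt1 than in both other lines, 49 higher and 24 lower in both resistant lines, and 8 opposite probes. The 32 probes lower in IGROV-1/Pt1 than in both other lines became 21 without IGROV-1/OHP replicate 1 and 18 without IGROV-1/Pt1 replicate 1. Those lower in IGROV-1/OHP became 9 without IGROV-1/Pt1 replicate 1 and 8 without replicate 2. The 3 opposite probes became 1 without IGROV-1/Pt1 replicate 1 or 2 or parental replicate 1.

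**Figure D3:**
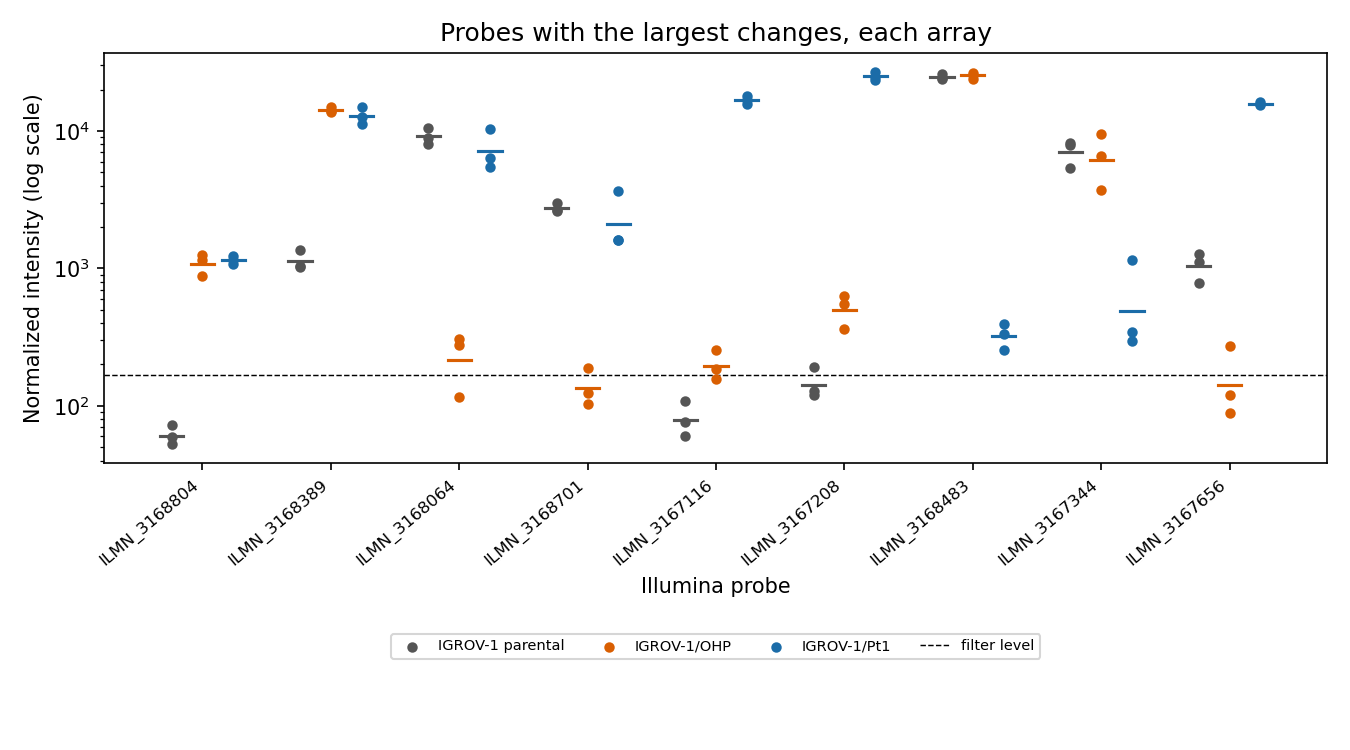
Normalized intensity (log scale) of the 9 named probes on each array, with points for the 3 arrays of each line and a bar at their geometric mean. The dashed line is the filter level of 167. ILMN_3167116 and ILMN_3167208 stand highest in IGROV-1/Pt1, and ILMN_3168804 and ILMN_3168389 stand higher in both resistant lines than in parental cells.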

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

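Among the tests given in this part, those of Pt1 RNA and of another RNA source on parental replicate 1, and those of a mixture, of dilution and of a shared axis in IGROV-1/OHP, were chosen after their results had been seen.

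The resistant lines differed from each other, by the direct test, at 117 probes, which is the test of whether their changes from the parental cells differ. Of the named probes, the log2 difference of IGROV-1/OHP minus IGROV-1/Pt1 was -5.05 at ILMN_3168064, -3.98 at ILMN_3168701, -6.42 at ILMN_3167116, -5.65 at ILMN_3167208, -6.78 at ILMN_3167656, 6.30 at ILMN_3168483 and 3.64 at ILMN_3167344. In each of these, all 3 arrays of one resistant line lay above all 3 of the other. This held at all 117 called probes, and the rule for named probes asks for it, so it adds no support. With 10 splits of the 6 arrays per comparison, a share under 0.05 cannot be reached. The real split gave 93 probes for IGROV-1/OHP against parental cells, 126 for IGROV-1/Pt1 against parental cells and 117 between the resistant lines. The highest count of the other splits was 0 in each comparison. For the 44 probes changed in the same direction in both resistant lines, 1 of 100 drawn splits of the 9 arrays, the real one, gave as many. The highest of the others was 28. With IGROV-1/Pt1 in the place of the parental line, the true lines give more than 44, since IGROV-1/Pt1 was higher than both others at 36 probes and lower at 32. That split was not among those drawn, as none of the others passed 28. Splits that mix lines also carry line differences into the residual spread, which can lower their counts. The draw therefore cannot decide whether a random grouping of the arrays is the source of that count. The splits cannot test overlap that comes from the shared parental arrays or from unrelated lists of real changes.

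Parental replicate 1 carried 20 probes at least 4-fold brighter than on replicate 2, by up to 95.1-fold, with a median rise of 3.43 on the log2 scale. Their median intensity was 3897 on replicate 1, 231 on replicate 2, 548 on replicate 3 and 255 on the arrays of the resistant lines. The values argue against a wrong label, since replicate 1 lay nearer to the other parental arrays than to the resistant line at 95.1% of 122 calls made without it, and against an intensity trend, since the median rise was 3.68 after cyclic loess. They argue against RNA of IGROV-1/Pt1, since the 10 probes measured at least 8-fold higher in IGROV-1/Pt1 than in both other lines had a median difference of -0.11 between replicates 1 and 2, and against RNA of IGROV-1/OHP, since replicate 1 was over 2-fold above the brightest IGROV-1/OHP array at 80.0% of the 20 probes. RNA from another source, present at a lower level in replicate 3, is a candidate explanation, as is a difference between the parental cultures, and no biological explanation was tested because the design names no group that separates them. Of the 14 probes at least 4-fold above all arrays of the resistant lines on replicate 1, 13 were higher on replicate 3 than on replicate 2. Their median log2 difference was 0.79, above all of 10000 random lists of probes matched on level. The lists were not matched on spread and treat probes as independent, so this rank does not measure the spread between replicates.

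In IGROV-1/OHP, 15 probes were at least 4-fold higher on replicate 2 than on replicate 3 and 11 were as much lower, with a median difference of 2.65. RNA of another line of the study raising the higher array is argued against as the whole cause, since that array lay above all parental and IGROV-1/Pt1 arrays at 73.1% of these probes, and so is dilution of the lower array by such RNA, since at probes at least 2-fold lower in IGROV-1/OHP each replicate lay nearer to the remaining IGROV-1/OHP arrays than to the other line at 80.0% or more. An intensity trend is argued against as well, since the median difference was 2.65 after cyclic loess. A shared axis of variation, such as culture state or RNA handling, may take part, because the difference correlated across probes at up to 0.45 in size with a difference within IGROV-1/Pt1. With differences within the parental line the correlation reached only 0.13, which keeps it open, and no biological explanation was tested. Deviations of same-numbered arrays of IGROV-1/OHP and IGROV-1/Pt1 correlated at 0.33 for replicates 2, 0.43 for replicates 3 and -0.18 for replicates 1.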

How the results depend on the processing

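Of the alternatives, normexp with offset 16, the intensity filters (the level on all 3 arrays of a line, or the median intensity as the level) and leaving out both parental replicate 1 and IGROV-1/OHP replicate 2 were chosen after the data had been seen. The 12 log2 changes of named probes kept their direction and their side of the threshold in all 252 values (21 alternatives each), with a largest shift of 0.76. Background correction, cyclic loess, median scaling, the filters, the prior, a fit of only the lines compared and leaving out both arrays kept the counts of the 3 comparisons and of shared changes within 1.5 times. The probes that set IGROV-1/OHP apart from both other lines moved more with scaling, from 13 higher to 6 after median scaling and from 14 lower to 22 after cyclic loess and 23 after median scaling. With array weights the counts against parental cells rose to 139 for IGROV-1/OHP and 219 for IGROV-1/Pt1. There were 200 between the resistant lines and 73 shared changes. Without weights these counts were 93, 126, 117 and 44. The cause of the rise was not tested. A measured change of at least 2-fold left 53 probes for IGROV-1/OHP against parental cells, 82 for IGROV-1/Pt1 against parental cells, 63 between the resistant lines and 28 shared, and an adjusted p under 0.01 from limma left 45, 81, 54 and 24, as stricter thresholds must. With the parental arrays divided, 4 of the 6 divisions moved the shared count by over 1.5 times, to 16, 17, 23 and 24. These fits have an arm of 1 parental array, assumed to vary like the other lines, so they change the precision as well as the sharing. Leaving out 1 array gave 60 to 102 probes for IGROV-1/OHP against parental cells, 102 to 148 for IGROV-1/Pt1 against parental cells, 71 to 130 between the resistant lines and 31 to 55 shared. The lowest of the first range was without IGROV-1/OHP replicate 1, and between the resistant lines the count was 76, 71 and 77 without IGROV-1/Pt1 replicate 1, 2 and 3.

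A replicate block reduced the count between the resistant lines to 77, with 35 higher and 42 lower in IGROV-1/OHP, against 61 and 56 without it. It gave 67 for IGROV-1/OHP and 118 for IGROV-1/Pt1 against parental cells and 38 shared. With the block, 3 probes were higher (13 without it) and 9 lower (14 without it) in IGROV-1/OHP than in both other lines, and 1 was opposite (3 without it). The numbers were not taken to pair the samples. Deviations of same-numbered arrays correlated at -0.27 to 0.43 across probes, above 0.1 in 3 of 9 pairs. Of the 9 arrays, 4 correlated best with their own number. The highest values were between IGROV-1/OHP and IGROV-1/Pt1, 0.43 for replicates 3 and 0.33 for replicates 2, against -0.18 for replicates 1. Differently numbered arrays of different lines reached at most 0.24. A link by number between the resistant lines therefore stays open. Not run were neqc and the detection p filters, since no label maps the unused table to samples. A match by values was not tried. The restriction to named human miRNA probes and the list tests lacked probe names. A chip block was not run either, as the column names of the unused table carry 1 chip number. The planned fits without background correction and on the deposited normalized values are the fit reported. Near the background floor, signal limits the folds of dim probes.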

Other observations

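No further test was chosen for this part. Probes that moved from below the filter level on all arrays of one line to at least 4-fold above it in another were unevenly spread. There were 5 that lay below the level in parental cells and were higher in IGROV-1/Pt1, and 0 the other way. Between IGROV-1/OHP and parental cells there was 1 in each direction. Between the resistant lines, 4 lay below the level in IGROV-1/OHP and 1 in IGROV-1/Pt1. The 10 probes measured at least 8-fold higher in IGROV-1/Pt1 than in both other lines ranged from 525 to 27072 on its arrays and from 50.6 to 6533 on the others. The 3 probes measured at least 8-fold lower in IGROV-1/OHP ranged from 65.8 to 307 on its arrays and from 769 to 10482 on the others. These counts were not tested against each other.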
